A study of Mus musculus with 6 samples.

How the data were processed

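The samples were chondrocytes, the cells that make cartilage, taken from the ribs of mouse embryos at embryonic day 18.5. There were 3 wild-type libraries and 3 libraries from conditional knockout embryos in which Cre recombinase under the Col2a1 promoter removed floxed Jab1 from cartilage cells. Per the labels' protocols, the tissue was digested with pronase and then overnight with collagenase, and cells were taken directly after isolation without culture. Also per the labels' protocols, libraries were stranded total RNA libraries depleted of ribosomal RNA, sequenced on a HiSeq instrument as single-end reads of 50 bases. The submitters' processing notes name STAR, Cufflinks and Cuffdiff with the mouse build mm10, and the labels' protocols also name CLC Genomics Workbench. Versions and settings were not given in the sources used here.

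The values are FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of each library) as the authors deposited them, in 1 table of 27734 genes and 6 library columns. Whether the between-library scaling of Cuffdiff was also applied is not stated. Columns were assigned by the group and number in their names, per the file headers. The descriptions number the libraries 0, 1 and 3 in each group and the columns 0, 1 and 2, so 4 columns were matched to a sample and 2 columns to their group only. Libraries are named here by column number. The labels do not say whether libraries came from separate embryos or litters, so p-values measure the spread between these libraries, which may be technical. Of the gene identifiers, 27578 (99.4%) matched GENCODE release M21 of the same build without their version, which gave coordinates and gene types. For 27 genes the symbol had become a whole number, and the GENCODE name was used in its place.

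Column totals ranged from 571180 to 631534 FPKM, and 13299 to 13706 genes had at least 1 FPKM per library. The 10 highest genes held 25.35 to 32.37% of each total. Read counts were not analysed here, so no counting intervals are given. Low values of small RNA genes nevertheless fell on common steps between libraries. The step in wild-type column 0 was 1.159 and 1.193 times that in wild-type columns 1 and 2, and 0.987, 1.44 and 1.136 times that in mutant columns 0, 1 and 2. If these steps are single reads, the ratios estimate the depth of each library relative to wild-type column 0, from 31 to 38 genes per library at the commonest step.

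FPKM values were transformed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 14012 genes. A linear model with 1 coefficient for genotype was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend=TRUE), two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. All adjusted p-values for genes come from this model unless another setting is named, and a gene is said to rise or fall when its adjusted p was under 0.05. Fold changes are on the log2(FPKM + 1) scale, mutant minus wild type, which understates changes of low genes. Values are given as mean ± SD with n = 3 libraries per group. With 3 libraries against 3, an exact permutation test cannot give a p under 0.1, so none is given. An exact 0 in these values can be a failed estimate, and for genes at 0 in every library of a group only the listed values are given.

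Before the data were examined, 36 gene lists (539 memberships, 15 of them for genes not analysed here) were fixed, covering cartilage, signalling, stress, cell cycle and other cell types. The 32 lists with at least 3 tested members, leaving out the sex-linked list, were tested with camera from limma at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. Genes named in the text were Cops5; Sox9, Col2a1, Acan, Col10a1, Ihh, Runx2, Mmp13 and Cdkn1a; the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, leaving out unnamed gene models, microRNAs, small nucleolar RNA symbols, pseudogenes and sex-linked genes; and, of each list, the 2 members with the smallest p and the 2 with the highest mean, of which some were left out, mostly where a list showed little. Results for some of these genes are not reported here. Other genes are named from among list members or passing genes and were chosen after their values were seen. An extra set of lists on the circadian clock, imprinted genes, ribosome biogenesis and X-linked genes that escape inactivation was also made after the data were seen.

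Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, a robust variance prior, library weights, leaving out each library in turn with the filter recomputed, and a replicate block. Alternatives added after seeing the data left out genes at 0 in all libraries of a group, left out chromosomes X and Y, kept protein-coding genes only, or added the level of Y-linked genes as a covariate. As a percent of each gene's highest value, that level averaged 0.3, 0 and 0.6% in wild-type columns 0, 1 and 2. It was 16.8, 98 and 85.7% in mutant columns 0, 1 and 2. With this covariate the genotype term rests largely on mutant column 0, so it does not separate sex from genotype. The fit was tested on simulated data for this comparison, drawn from the real means and spreads of 14012 genes with 200 genes changed. Over 20 simulations it recovered 61 to 81 (mean 68.2) of 100 changed genes at a log2 change of 1 and 80 to 95 (mean 89) of 100 at a log2 change of 2, while 2 to 14 unchanged genes were called. The simulated noise was drawn independently for each gene, without a deviating library or a difference of sex. These rates need therefore not hold for the real libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.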

Results

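Gene expression was measured by RNA sequencing in chondrocytes freshly isolated from the ribs of mouse embryos late in gestation. The 6 libraries comprised 3 from wild-type embryos and 3 from embryos in which Jab1 was removed in Col2a1-expressing cells. Jab1, encoded by Cops5, is the subunit of the COP9 signalosome that takes the ubiquitin-like protein Nedd8 off cullins. The comparison asks which genes change in chondrocytes when Jab1 is lost. The title of wild-type column 0 carries another day of the month (30) than the titles of the other dated columns (24), and no other library shares its date. Library columns held 571180 to 631534 FPKM in total. Correlations of log2 values between libraries were 0.895 to 0.919 within groups and 0.865 to 0.898 between groups.

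Cops5 (chromosome 1, 10024601 to 10038168, mm10) fell in every mutant library but was still measured. Its values were 42.3, 39.8 and 40.1 FPKM in wild-type and 17.0, 18.0 and 17.2 FPKM in mutant columns 0, 1 and 2. This gave 40.7 ± 1.39 FPKM in wild type and 17.4 ± 0.534 in mutant libraries (SD, n = 3), a log2 fold change of -1.18 (SE 0.0599, limma adjusted p = 6.5e-04). The values cover the whole gene and not the floxed part alone. Among the other 9 COP9 signalosome subunits none passed the limma test, with 1 higher and 1 lower at an unadjusted p under 0.05. Of all 14012 genes tested, 3459 had an unadjusted limma p under 0.05. Counts at this threshold, here and for the lists below, are to be read against that share. None passed when adjusted over the list alone. The higher one, Cops8, measured 24.6 ± 1.38 FPKM in wild type and 28.9 ± 1.43 in mutant libraries (adjusted p = 0.13), and the lower one, Cops9 (listed as Myeov2), 115 ± 4.72 against 97.6 ± 6.33 FPKM (adjusted p = 0.14). Cops3 measured 86.0 ± 6.48 against 75.1 ± 3.90 FPKM (adjusted p = 0.22) and was not among these. Of 22 genes of cullin ligases and neddylation 1 rose, Fbxw7, the substrate receptor of an SCF ligase, from 11.5 ± 0.832 to 18.0 ± 2.01 FPKM (adjusted p = 0.033), and 1 rose when adjusted over the list alone. The number rising was 0 without wild-type column 0, 1 or 2 or mutant column 0, 1 or 2. Ddb1, an adaptor of Cul4 ligases, measured 254 ± 2.82 FPKM in wild type and 212 ± 6.03 in mutant libraries and did not pass (adjusted p = 0.081).

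Of 23 tested targets of p53, the transcription factor that responds to DNA damage and other stress, 13 rose in mutant chondrocytes, none fell and 10 did not pass, and 20 rose when adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 18.2 ± 6.19 to 65.0 ± 7.73 FPKM (log2 fold change 1.82, SE 0.230, adjusted p = 0.017). Without wild-type columns 0 and 2 or mutant column 2, Cdkn1a no longer passed (adjusted p = 0.072, 0.068 and 0.076), nor did it with the Y-linked level as a covariate (adjusted p = 0.073). Its log2 fold change ranged from 1.68 to 2.07 over all settings. Eda2r, a receptor of the tumor necrosis factor family on the X chromosome, rose from 0.718 ± 0.102 to 8.80 ± 0.743 FPKM, and Trp53inp1 from 7.22 ± 1.71 to 28.6 ± 1.90 FPKM. Ccng1 rose from 85.4 ± 2.11 to 174 ± 20.2 FPKM, Phlda3 from 11.8 ± 2.29 to 41.4 ± 5.87 FPKM and Mdm2, the ligase that degrades p53, from 29.7 ± 2.72 to 50.0 ± 4.51 FPKM. The median log2 fold change of the list was 1.01 (camera adjusted p = 3.1e-13; adjusted p = 0.45 with an estimated correlation). The list median per mutant library, against the wild-type mean, was 0.87, 0.71 and 1.11. The number of p53 targets that rose was 5 without wild-type column 2, 6 without wild-type column 0 or mutant column 2 and 7 without wild-type column 1, and 6 with the Y-linked level as a covariate. Of 16 genes of the apoptosis machinery 1 rose, Bax, a p53 target that permeabilises mitochondria, from 46.6 ± 3.64 to 101 ± 16.2 FPKM (adjusted p = 0.016), and 2 rose when adjusted over the list alone. The list was not called (camera adjusted p = 0.099). The number rising was 0 without wild-type column 0, 1 or 2. Y-linked genes were present in the mutant and near 0 in the wild-type libraries, with Ddx3y at 0.157, 0.0281 and 0.450 FPKM in wild-type and 7.78, 46.1 and 36.0 FPKM in mutant columns 0, 1 and 2, and Xist at 63.1, 64.6 and 65.9 and 37.3, 0.0176 and 0.0244 FPKM.

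**Figure D1:**
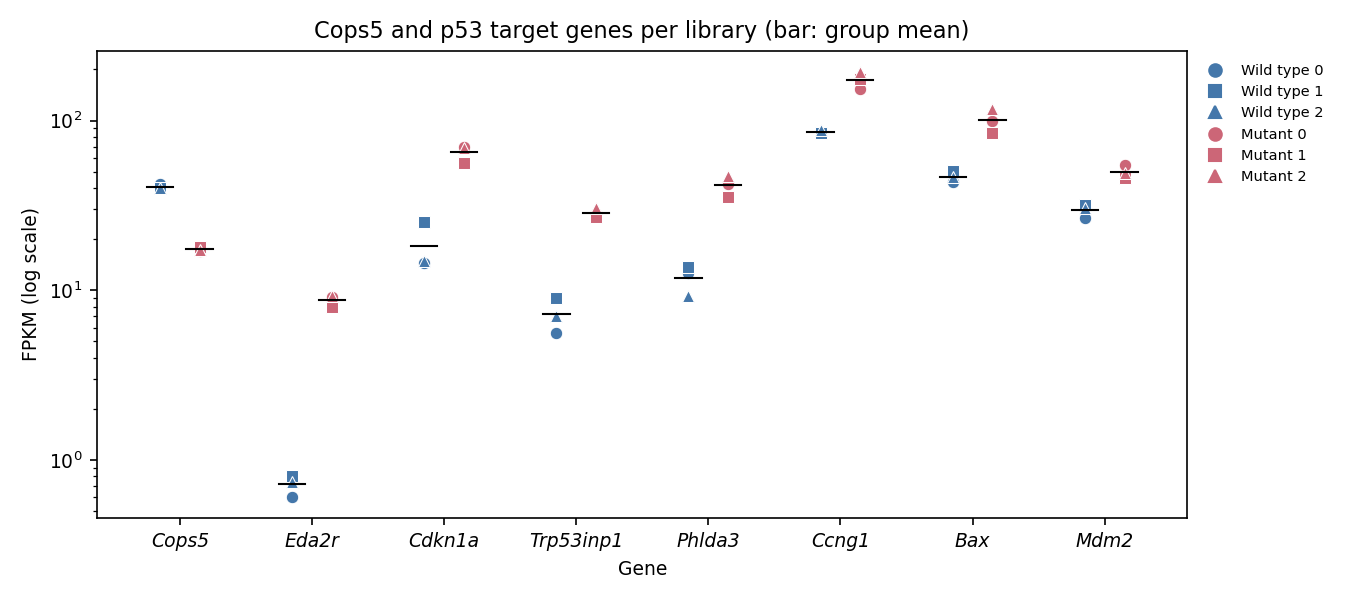
FPKM on a log axis of Cops5 and 7 p53 target genes, with 1 point per library (blue, wild type; red, mutant) and a bar at each group mean of 3 libraries. Cops5 lies lower and each of the p53 targets higher in all 3 mutant libraries than in all 3 wild-type libraries.

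Across all 14012 genes tested, 850 changed, with 487 higher and 363 lower in mutant cells, and 243 changed at least 2-fold. Of all genes tested, 4510 (32.2%) had groups that did not overlap, against 10% by chance for 3 libraries against 3. The counts depended on single libraries, and these fits had fewer libraries. The number of changed genes was 174, 192 and 178 without wild-type columns 0, 1 and 2, and 288 and 197 without mutant columns 1 and 2. It was 666 without mutant column 0. Other settings gave 461 without the filter on low values, 1488 with library weights, 1373 with protein-coding genes only and 478 with the Y-linked level as a covariate, of which 201 were among the 850. Genes higher numbered 104, 125 and 99 and genes lower 70, 67 and 79 without wild-type columns 0, 1 and 2, while without mutant columns 1 and 2 there were 183 and 131 higher and 105 and 66 lower. Of the 850 genes, 156, 176 and 162 were called again without wild-type columns 0, 1 and 2, and 483, 243 and 183 without mutant columns 0, 1 and 2. At least 2-fold changes numbered 139, 149 and 144 without wild-type columns 0, 1 and 2 and 149 without mutant column 2.

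Of 16 tested targets of NRF2, the regulator of antioxidant genes, 6 rose, none fell and 10 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose from 10.1 ± 1.05 to 22.4 ± 1.95 FPKM (adjusted p = 0.0073). Txnrd1, thioredoxin reductase, rose from 29.0 ± 2.20 to 49.4 ± 3.00 FPKM, Nqo1 from 75.7 ± 10.7 to 161 ± 30.8 FPKM and Gstm1 from 14.6 ± 2.29 to 40.7 ± 7.34 FPKM. The ferritin genes Ftl1 and Fth1 measured 243 ± 21.7 against 336 ± 32.4 FPKM and 179 ± 24.4 against 258 ± 18.6 FPKM without passing (adjusted p = 0.068 and 0.066). The number of members that rose was 1 without wild-type column 2 and 2 without wild-type column 0 or mutant column 2, and 2 with the Y-linked level as a covariate. The list median was 0.52 (camera adjusted p = 1.5e-05; adjusted p = 0.45 with an estimated correlation). In the unfolded protein response list 2 of 20 members rose, Dnajc3 from 42.1 ± 1.38 to 58.4 ± 3.13 FPKM and Manf from 125 ± 0.850 to 168 ± 9.23 FPKM, while the chaperone Hspa5 measured 615 ± 20.5 FPKM in wild type and 803 ± 57.3 in mutant libraries and did not pass (adjusted p = 0.073). Calr measured 403 ± 3.96 against 654 ± 176 FPKM (adjusted p = 0.11). When adjusted over the list alone 3 rose, and the number over all genes was 0 without wild-type column 0, 1 or 2 or mutant column 1 or 2. That list had a median of 0.31 (camera adjusted p = 0.0021; adjusted p = 0.54 with an estimated correlation). In mutant columns 0, 1 and 2 the medians of the list were 0.52, 0.13 and 0.18, and without mutant column 0 the camera adjusted p was 0.018. Of 10 inflammatory genes 2 rose, Ptgs2, which encodes cyclooxygenase-2, from 4.95 ± 1.20 to 17.7 ± 1.01 FPKM and the adhesion molecule Icam1 from 1.46 ± 0.241 to 4.35 ± 1.20 FPKM (camera adjusted p = 0.0033 for the list; adjusted p = 0.45 with an estimated correlation). Of the inflammatory genes 6 rose when adjusted over the list alone, and the number over all genes was 1 without wild-type column 0, 1 or 2 or mutant column 1 or 2. The inflammatory list was not called without the filter on low values or with the Y-linked level as a covariate (camera adjusted p = 0.063 and 0.18), and none rose with the covariate. Over all other settings the number of inflammatory genes that rose ranged from 0 to 5. Nfkb1 measured 14.5 ± 0.730 against 18.0 ± 1.18 FPKM (adjusted p = 0.078). None of 5 tested interferon-stimulated genes passed in limma, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.022, down; adjusted p = 0.45 with an estimated correlation). Of the interferon-stimulated genes 3 fell when adjusted over the list alone, and the list was not called without mutant column 0 or with library weights (camera adjusted p = 0.095 and 0.074).

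Of 13 genes that respond to bone morphogenetic proteins (BMPs), signals that drive chondrocyte growth and maturation, 4 rose in mutant cells, none fell and 9 did not pass, and 8 rose and 1 fell when adjusted over the list alone. Id3 and Id4, inhibitors of helix-loop-helix factors, rose from 117 ± 16.9 to 221 ± 41.5 FPKM and from 40.7 ± 1.63 to 70.4 ± 6.35 FPKM. Bambi, a decoy receptor, rose from 15.7 ± 1.15 to 34.0 ± 5.60 FPKM and the transcription factor Atoh8 from 14.1 ± 1.60 to 51.9 ± 17.0 FPKM. Id2 measured 166 ± 11.2 against 253 ± 57.2 FPKM (adjusted p = 0.10). The number of members that rose was 0 without wild-type column 0, 1 or 2 and 1 without mutant column 2, and 7 with protein-coding genes only. In mutant columns 0, 1 and 2 the medians of the BMP response list were 0.86, 0.43 and 0.53. The list median was 0.61 (camera adjusted p = 7.7e-05; adjusted p = 0.45 with an estimated correlation). Among 14 BMP ligands, receptors and SMADs, Bmp6 rose from 15.9 ± 3.01 to 34.0 ± 3.08 FPKM and Smad1, a transducer of the signal, fell from 22.0 ± 1.05 to 15.1 ± 0.606 FPKM, with the list not called (camera adjusted p = 0.19). In that list 2 rose and 1 fell when adjusted over the list alone. The number rising was 0 without wild-type column 0 or 2 or mutant column 1 or 2 and 2 without mutant column 0. The number falling was 0 without wild-type column 0, 1 or 2 or mutant column 1 or 2. Of 13 genes of the TGF-beta list Tgfbr2 alone rose, from 16.7 ± 1.03 to 21.4 ± 0.453 FPKM, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.52 with an estimated correlation). Ctgf, a matrix-associated target of the pathway, measured 139 ± 24.5 against 257 ± 51.2 FPKM and did not pass (adjusted p = 0.057). Over all genes the number rising was 0 without wild-type column 0, 1 or 2 or mutant column 0 or 1, while other settings gave 0 (with the Y-linked level as a covariate) to 5 (with protein-coding genes only).

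Of 8 tested genes of FGF signalling 3 passed. Dusp6, a feedback phosphatase, rose from 2.80 ± 0.808 to 9.80 ± 2.00 FPKM (adjusted p = 0.019) and the transcription factor Etv5 from 1.01 ± 0.352 to 2.95 ± 0.571 FPKM. The remaining one, Fgfr2, was listed at 0 in all wild-type libraries, and the list median without it was 0.63 (camera adjusted p = 1.5e-05 with it; adjusted p = 0.45 with an estimated correlation). In the FGF list 5 rose when adjusted over the list alone, Fgfr2 among them. Leaving out Fgfr2, the number over all genes was 2, but 0 without wild-type column 0 or 1 or mutant column 1 and 1 without wild-type column 2 or mutant column 2. Fgfr3 measured 322 ± 17.4 against 352 ± 59.1 FPKM (adjusted p = 0.64). In Hedgehog signalling 2 of 10 tested members fell and none rose. Gli1, a transcription factor and direct target of the pathway, fell from 13.1 ± 2.65 to 3.12 ± 0.488 FPKM (log2 fold change -1.76, SE 0.161, adjusted p = 0.0071), and the receptor Ptch1, also a direct target, fell from 26.7 ± 2.47 to 14.3 ± 3.38 FPKM (adjusted p = 0.045). The ligand gene Ihh measured 11.5 ± 1.70 FPKM in wild type and 8.08 ± 0.990 in mutant libraries and did not pass (adjusted p = 0.10). The list had a median of -0.18 (camera adjusted p = 0.019; adjusted p = 0.53 with an estimated correlation). Of the Hedgehog genes 3 fell when adjusted over the list alone, and the number over all genes was 1 without wild-type column 0, 1 or 2 or mutant column 1 or 2. The list was not called without mutant columns 1 and 2 (camera adjusted p = 0.061 and 0.069), nor with the Y-linked level as a covariate, where none fell and the median was 0.07 (camera adjusted p = 0.67). Its medians per mutant library, in columns 0, 1 and 2, were 0.02, -0.26 and -0.48. None of 8 Wnt response genes passed in limma, with 1 higher and 0 lower at an unadjusted p under 0.05.

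**Figure D2:**
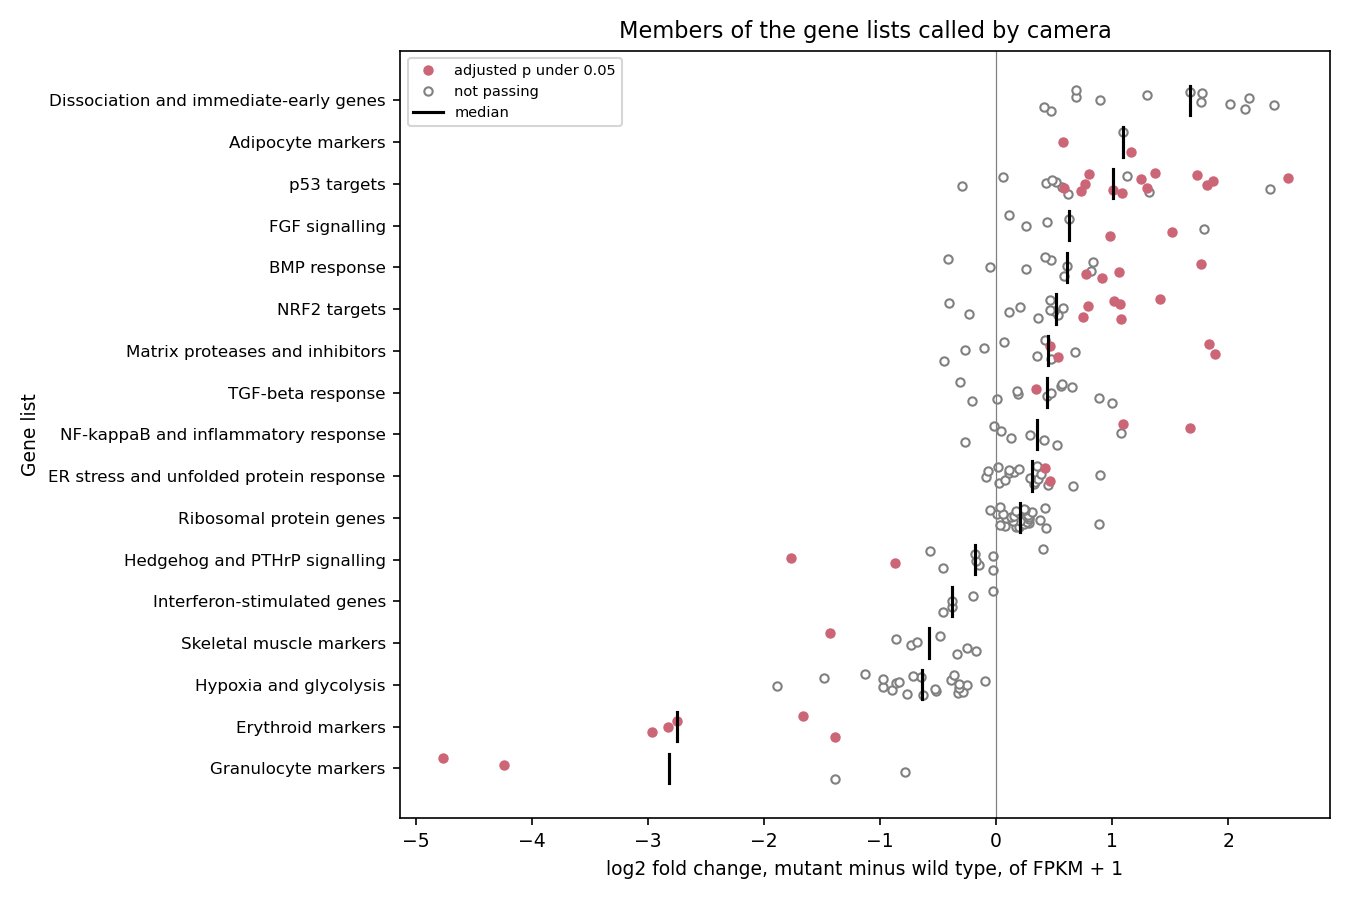
Log2 fold changes, mutant minus wild type, of the members of the 17 gene lists called by camera, 1 point per gene (filled, adjusted p under 0.05; open, not passing) with a black bar at each list median. Genes listed at 0 in a whole group are left out, and the medians run from -2.81 for granulocyte markers to 1.67 for immediate-early genes.

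Cartilage genes gave few calls. Of 22 tested members of the cartilage list 1 rose, 2 fell and 19 did not pass. The secreted factor Cytl1 rose from 88.9 ± 15.6 to 315 ± 61.4 FPKM (adjusted p = 0.0095), while the matrix proteins Comp and Matn3 fell from 801 ± 45.5 to 508 ± 36.0 FPKM and from 359 ± 31.8 to 239.9 ± 24.4 FPKM. Sox9, the master regulator of the lineage, measured 75.7 ± 1.79 FPKM in wild type and 55.3 ± 15.9 in mutant libraries (adjusted p = 0.22) and the proteoglycan gene Acan 965 ± 85.2 FPKM in wild type and 823 ± 604 in mutant libraries (adjusted p = 0.59). Acan was 1516, 540.5 and 412 FPKM in mutant columns 0, 1 and 2, and without column 0 it passed with a log2 fold change of -1.03 (adjusted p = 0.041). Col9a3 measured 2438 ± 299.6 against 1852 ± 411 FPKM (adjusted p = 0.26). When adjusted over the list alone 2 rose and 2 fell, and the number falling over all genes was 0 without wild-type column 0, 1 or 2 or mutant column 1 or 2. With the Y-linked level as a covariate none of the cartilage list rose or fell, and without the filter on low values none fell. Col2a1 was not analysed here. The cartilage list median was -0.30 (camera adjusted p = 0.11). Per library it was 0.01, -0.01 and -0.06 in wild-type and -0.03, -0.32 and -0.49 in mutant columns 0, 1 and 2. Mutant column 0 thus lay near wild type and mutant columns 1 and 2 lower. None of 16 prehypertrophic and hypertrophic genes passed in limma, though 2 fell with the Y-linked level as a covariate, with 2 higher and 4 lower at an unadjusted p under 0.05. Col10a1 measured 449.6 ± 65.2 FPKM in wild type and 481 ± 248 in mutant libraries (adjusted p = 0.94), Runx2 12.8 ± 2.18 FPKM in wild type and 9.61 ± 1.48 in mutant libraries (adjusted p = 0.20) and Mmp13 68.0 ± 31.1 FPKM in wild type and 93.3 ± 46.7 in mutant libraries (adjusted p = 0.63). None passed when adjusted over the list alone. Spp1, which encodes osteopontin, measured 746 ± 257 against 1673 ± 686 FPKM (adjusted p = 0.18). Of 13 matrix proteases and inhibitors 5 passed, 1 of them Htra1, listed at 0 in all wild-type libraries. The other 4 were Mmp3, stromelysin, which rose from 0.616 ± 0.142 to 4.93 ± 1.69 FPKM, Mmp2 from 80.2 ± 2.22 to 111 ± 3.83 FPKM, Timp3 from 28.6 ± 11.4 to 104 ± 15.1 FPKM and Timp2 from 45.0 ± 3.96 to 65.6 ± 5.47 FPKM. When adjusted over the list alone 5 rose, Htra1 among them, and 1 fell. Leaving out Htra1, the number rising over all genes was 0 without wild-type column 0 or 2 or mutant column 1, 1 without wild-type column 1 or mutant column 2 and 2 without mutant column 0. The list median without Htra1 was 0.45 (camera adjusted p = 0.0033 with it; adjusted p = 0.45 with an estimated correlation). Per mutant library, in columns 0, 1 and 2, the protease medians were 0.05, 0.46 and 0.41. With the Y-linked level as a covariate none rose other than Htra1, 1 fell and the list was not called (camera adjusted p = 0.22).

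No gene of the cell cycle lists passed in limma. Among 22 genes of DNA replication 4 were higher and 0 lower at an unadjusted p under 0.05, and among 22 genes of mitosis 0 and 0. The medians of the mitosis list were 0.38, -0.25 and -0.38 in mutant columns 0, 1 and 2, so column 0 lay on the other side of the wild-type mean, and they were 0.23, -0.23 and 0.00 in wild-type columns 0, 1 and 2. None passed when adjusted over the list alone in these lists, nor in the Wnt, ribosomal protein and histone lists. Mki67, a marker of dividing cells, measured 37.6 ± 7.33 FPKM in wild type and 29.6 ± 9.36 in mutant libraries (adjusted p = 0.42). None of 28 ribosomal protein genes passed in limma (8 higher at an unadjusted p under 0.05), with a median of 0.20 (camera adjusted p = 1.7e-04; adjusted p = 0.53 with an estimated correlation). That list was not called with the Y-linked level as a covariate (camera adjusted p = 0.44). None of 21 replication-dependent histone genes passed either, with 4 lower at an unadjusted p under 0.05, among them the linker histone gene Hist1h1c at 232 ± 55.7 FPKM in wild type and 135 ± 14.5 in mutant libraries. Of the mitochondrially encoded list 7 genes were not analysed here and the others did not reach the filter.

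Erythroid and granulocyte markers were lower in mutant libraries. All 5 tested erythroid markers fell, among them the globin genes Hbb-bs, from 143 ± 12.8 to 20.0 ± 13.6 FPKM, and Hba-a1, from 29.4 ± 1.06 to 3.85 ± 2.11 FPKM, with a list median of -2.75 (camera adjusted p = 1.5e-05; adjusted p = 0.45 with an estimated correlation). The number of erythroid markers that fell was 0 without wild-type column 0, 1 or 2 or mutant column 2. Adjusted over the list alone all 5 fell. Of 4 granulocyte markers 2 fell, the calprotectin subunits S100a8, from 47.7 ± 25.5 to 1.67 ± 1.53 FPKM, and S100a9, from 67.0 ± 34.7 to 1.47 ± 1.24 FPKM (camera adjusted p = 0.0016; adjusted p = 0.45 with an estimated correlation). All 4 granulocyte markers fell when adjusted over the list alone, and the number over all genes was 1 without wild-type column 0, 1 or 2 or mutant column 2, and 0 with the Y-linked level as a covariate. None of 10 macrophage markers passed in limma (2 lower and 1 higher at an unadjusted p under 0.05), with Lyz2 at 31.1 ± 12.8 FPKM in wild type and 7.57 ± 4.16 in mutant libraries, and 2 fell when adjusted over the list alone. Of 8 skeletal muscle markers 1 fell, Tnnt3, from 141 ± 19.9 to 51.8 ± 11.0 FPKM (camera adjusted p = 0.019 for the list; adjusted p = 0.54 with an estimated correlation). When adjusted over the list alone 2 muscle markers fell, and the number over all genes was 0 without wild-type column 0, 1 or 2 or mutant column 2. The muscle list was not called without wild-type column 2 or mutant column 2 (camera adjusted p = 0.076 and 0.17), nor with the Y-linked level as a covariate (camera adjusted p = 0.20). Of 12 fibroblast and perichondrium markers 2 rose, Twist1 from 4.16 ± 0.352 to 7.39 ± 0.614 FPKM and Prrx1 from 19.9 ± 1.74 to 31.6 ± 2.40 FPKM, and 2 fell, the matrix proteoglycans Lum from 625 ± 34.4 to 343 ± 66.5 FPKM and Dcn from 504 ± 30.0 to 341 ± 31.8 FPKM. Adjusted over the list alone the fibroblast counts were 2 rising and 2 falling. Over all genes, the number rising was 0 without wild-type column 0, 1 or 2 or mutant column 1 or 2 and 1 without mutant column 0. The number falling was 0 without wild-type column 0, 1 or 2 or mutant column 2 and 1 without mutant column 0 or 1. With the Y-linked level as a covariate no fibroblast marker rose and 1 fell, and without the filter on low values none fell. Of 8 osteoblast markers Smpd3 fell, from 174 ± 12.3 to 111 ± 12.5 FPKM, also when adjusted over the list alone, and the number falling was 0 without wild-type column 0, 1 or 2 or mutant column 1 or 2, and 0 without the filter on low values or with the Y-linked level as a covariate. Of 7 adipocyte markers only 3 were tested, as the others did not reach the filter. Of the 3 tested, 2 rose, Pparg from 5.36 ± 0.673 to 13.3 ± 2.04 FPKM and Lpl from 9.32 ± 1.22 to 14.4 ± 1.37 FPKM (camera adjusted p = 0.0093, or 0.45 with an estimated correlation). Both also rose when adjusted over the list alone, and the number over all genes was 0 without wild-type column 0, 1 or 2 or mutant column 2 and 1 without mutant column 1. With the Y-linked level as a covariate neither passed and the adipocyte list was not called (camera adjusted p = 0.33). None of 4 osteoclast, 5 endothelial, 2 neural or 1 epithelial marker tested passed in limma, with 0, 1, 0 and 1 higher at an unadjusted p under 0.05. In mutant columns 0, 1 and 2 the list medians were -0.52, -0.25 and 0.35 for osteoblast, -0.23, 0.39 and 1.85 for osteoclast and -0.51, 0.60 and 0.81 for endothelial markers. Adjusted over the list alone, 1 endothelial and 1 epithelial marker rose.

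Mutant column 0 stood apart in genes that respond quickly to stimuli and in genes of hypoxia. The immediate-early gene Fos was 587, 18.3 and 20.0 FPKM in mutant columns 0, 1 and 2 and 9.73, 8.60 and 14.9 FPKM in wild type, and Egr1 was 145, 10.1 and 9.29 against 3.16, 5.11 and 6.01 FPKM. None of 13 immediate-early genes passed in limma (2 higher at an unadjusted p under 0.05), with a median of 1.67 (camera adjusted p = 0.0031; adjusted p = 0.60 with an estimated correlation). Without mutant column 0, 2 immediate-early genes rose, with protein-coding genes only 1 rose, and with the Y-linked level as a covariate 11 rose. The covariate fit rests largely on mutant column 0. The hypoxia gene Car9 was 0.671, 19.2 and 10.1 FPKM in mutant columns 0, 1 and 2 against 22.3, 44.2 and 17.1 FPKM in wild type, and the glycolysis gene Ldha 241, 528 and 514 against 687, 689.6 and 618 FPKM. None of 22 hypoxia and glycolysis genes passed in limma (6 lower at an unadjusted p under 0.05), with a median of -0.64 (camera adjusted p = 7.7e-05; adjusted p = 0.54 with an estimated correlation). With the Y-linked level as a covariate 8 hypoxia and glycolysis genes fell. Per mutant library the medians of that list were -1.16, -0.20 and -0.46 against the wild-type mean. In wild-type columns 0, 1 and 2 they were 0.11, 0.16 and -0.28, so mutant column 1 lay within the wild-type range.

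**Figure D3:**
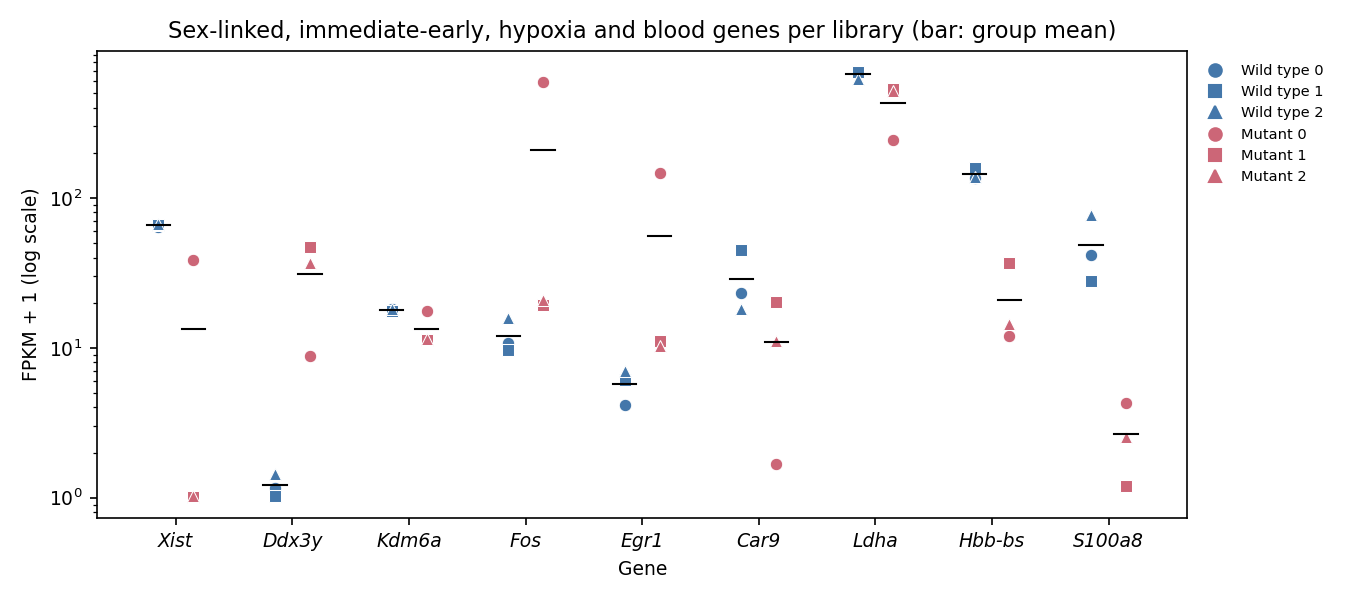
FPKM + 1 on a log axis of 9 genes, with 1 point per library (blue, wild type; red, mutant) and a bar at each group mean of 3 libraries. Mutant column 0 (red circle) keeps Xist, has less Ddx3y and more Fos and Egr1 than the other mutant libraries, and Hbb-bs and S100a8 lie lower in all 3 mutant libraries.

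The 10 largest rises picked by the rule were all genes listed at 0 in every wild-type library, so no fold can be given. They were AY036118, Oat, AF357428, Fgfr2, Bub3, Htra1, Zc3h7a, Nsmce4a, Mettl10 and Zranb1. AF357428 is annotated as a small nucleolar RNA, but its symbol was not among those left out. In mutant columns 0, 1 and 2, Oat was listed at 178, 171 and 181 FPKM, Fgfr2 at 128, 118 and 113 FPKM and Bub3, a mitotic checkpoint gene that dividing cells use, at 57.1, 46.8 and 54.3 FPKM. AY036118 was listed at 13193, 168 and 1764 FPKM, and it lies within Rn18s-rs5, annotated as a ribosomal RNA gene (chromosome 17, 39846353 to 39848827, mm10) and also at 0 in all wild-type libraries, with 79.5, 3.73 and 24.3 FPKM in mutant columns 0, 1 and 2. Of the 850 changed genes 37 were at 0 in all wild-type and 9 at 0 in all mutant libraries, and 851 genes changed when such genes were left out of the test. Among all genes tested, 215 were at 0 in all wild-type and 177 at 0 in all mutant libraries. Fgfr2 is annotated over chromosome 7, 130162451 to 133123350 (mm10), and all 49 genes of the table inside that span were at 0 in all 3 wild-type libraries. Among the 50 genes flanking it, none of the 19 with at least 1 FPKM in all mutant libraries was at 0 in all wild-type libraries.

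**Figure D4:**
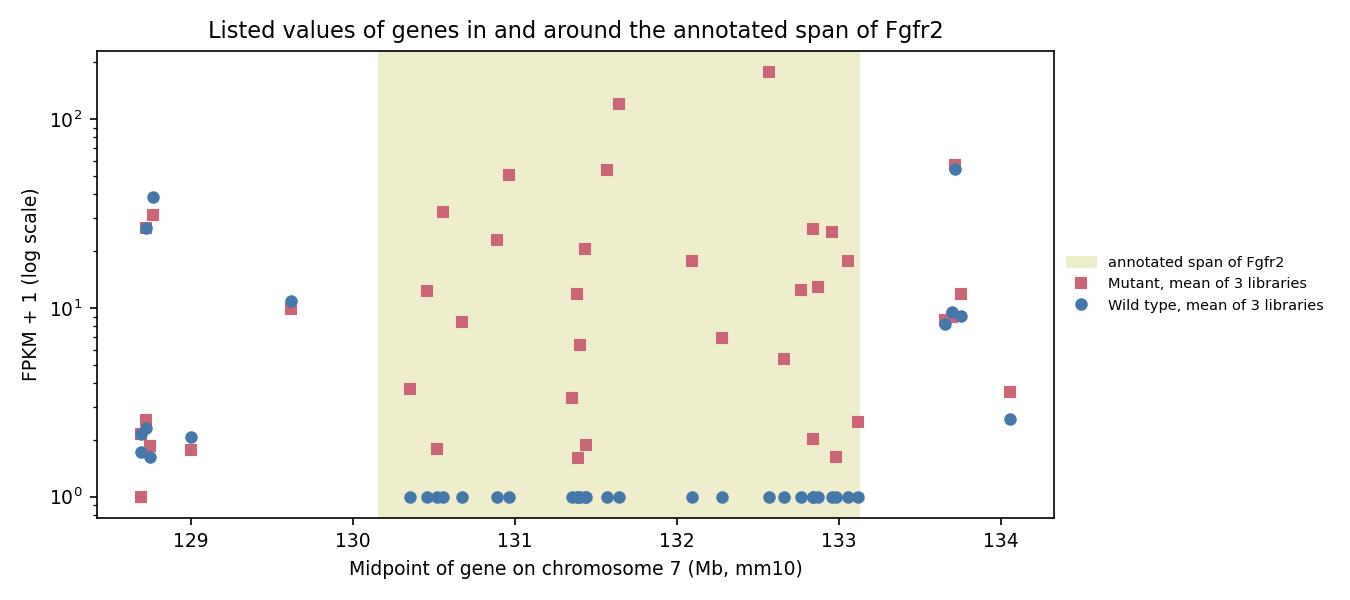
Mean FPKM + 1 of 3 libraries per group on a log axis against gene position on chromosome 7 (mm10) for genes with at least 1 FPKM in some library. Inside the shaded span annotated for Fgfr2 every wild-type value (blue) is listed at 0 while mutant values (red) are above 0, and the wild-type means of the plotted genes on both sides are above 0.

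Among genes with values above 0 in both groups, chosen after values were seen, the largest rises were Ephx1, an epoxide hydrolase, from 3.19 ± 0.800 to 26.7 ± 2.67 FPKM (log2 fold change 2.74, SE 0.152, adjusted p = 9.7e-04), then Eda2r, Ddit4l, an inhibitor of mTOR signalling, from 2.24 ± 0.752 to 16.1 ± 3.61 FPKM, and Penk, the precursor of enkephalins, from 14.9 ± 0.731 to 74.2 ± 7.01 FPKM. Gpx3, a secreted glutathione peroxidase, rose from 6.71 ± 1.87 to 30.4 ± 3.41 FPKM. The 10 largest falls began with Rn7sk, a small nuclear RNA listed at 49844, 42394 and 45407 FPKM in wild-type and at 0 in all mutant libraries. S100a9, S100a8, Stfa2l1, Stfa1, Stfa2, Retnlg and Stfa3 followed, genes known from granulocytes, with Stfa3 falling from 9.81 ± 2.58 to 0.274 ± 0.137 FPKM. Pcp4, a calmodulin-binding peptide, fell from 27.5 ± 8.92 to 1.06 ± 0.440 FPKM (adjusted p = 0.0026), and Hbb-bs was the last of the 10. Copies in the Stfa and globin families are near-identical, so values of single members are uncertain.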

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

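The alternatives on zero-listed genes, chromosomes X and Y, gene type and the Y-linked level, and the splits of the libraries, were chosen after seeing the data. Cops5 fell in every setting run, with a log2 fold change from -1.23 to -1.15 and a limma adjusted p from 9.4e-05 to 0.0096. Each of the 850 genes that was tested in a setting kept its sign there. All 850 had groups that did not overlap, so leaving out a library or changing the pseudocount or filter could not change a sign. For those settings the kept signs are no evidence of stability. Without the filter on low values 461 genes changed (295 higher and 166 lower), with library weights 1488 (816 and 672), with protein-coding genes only 1373 (741 and 632) and with the Y-linked level as a covariate 478 (320 and 158, with 367 at least 2-fold); the cause was not tested. Leaving out 1 library gave 174 to 666 changed genes, 99 to 377 higher, 66 to 289 lower and 139 to 258 at least 2-fold, from fewer libraries. Camera called 17 of 32 lists, but 0 with an estimated correlation, and fry called 11 in a direction. Fry called the p53 (fry adjusted p = 0.0040), NRF2, BMP response, FGF, inflammatory, interferon, protease, apoptosis, erythroid, granulocyte and adipocyte lists. Among lists called by camera, fry did not call the TGF-beta, Hedgehog, ribosomal protein, unfolded protein response, muscle, hypoxia and immediate-early lists (fry adjusted p = 0.076 to 0.24). With the replicate block 621 genes changed, but same-numbered libraries did not deviate together (r = -0.033 and -0.042 for the numbers 0 and 1), so the numbers are not read as pairs. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many changed genes came from 1 of the 10 splits (850, highest other 8), as many higher genes from 1 (487 and 6), lower genes from 1 (363 and 6) and at least 2-fold changes from 1 (243 and 8). As many lists called by camera came from 2 splits (17, highest other 17). Every other split called 7 to 17 lists, so calls by camera at the fixed correlation did not require the full genotype grouping. Each of these splits still set unequal numbers of wild-type libraries against each other, so part of the genotype difference remained. They therefore cannot tell false calls from calls of that remaining difference. With library weights the log2 fold change of Col10a1 changed sign (0.23), and the cause was not tested. With the Y-linked level as a covariate those of Acan (0.95), Col9a3 (0.055), Mki67 (0.24), Mmp13 (-0.51) and Xist (0.28) did. None of these reversed values passed, while Col10a1 passed with that covariate (-1.54). The genotype term of the covariate fit rests largely on mutant column 0. In that column Acan was 1516 FPKM against a wild-type mean of 965. Col10a1 was 195 FPKM there against 449.6 and Mmp13 49.3 against 68.0. Leaving out 1 library moved Col10a1 between -0.38 and 0.48 and Fgfr3 between -0.016 and 0.21. Depth limits the values of low genes, and no read counts were analysed here.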

Other observations

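The tests of explanations in this part, its lists of clock, imprinted, ribosome biogenesis and X-linked genes, and the Y-linked level as a covariate were chosen after the data were seen, while the 850 changed genes and the cell type lists belong to the planned comparison.

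Genes of the circadian clock included 3 that fell among 14 tested, with none rising. Per3 fell from 7.79 ± 1.21 to 2.70 ± 0.240 FPKM (adjusted p = 0.0090), and Nr1d1 and Nr1d2, nuclear receptors that repress clock genes, fell from 5.24 ± 0.399 to 2.55 ± 0.351 FPKM and from 15.3 ± 0.335 to 9.49 ± 1.63 FPKM. The list was not called (camera adjusted p = 0.056), with a median log2 fold change of -0.15. Without mutant column 0 the median was -0.34 and 4 fell. Over the other settings run, Per3 lost its call in 1 of 19, Nr1d1 in 4 of 18 and Nr1d2 in 6 of 19. Of 15 imprinted genes linked to growth, Mest rose from 408 ± 9.06 to 529 ± 11.6 FPKM, and Magel2 and Grb10, an adaptor that restrains insulin signalling, fell from 12.3 ± 1.08 to 3.79 ± 0.0910 FPKM and from 462 ± 20.3 to 341 ± 13.6 FPKM (camera adjusted p = 0.0013 for the list; adjusted p = 0.27 with an estimated correlation). Without mutant column 0, 0 imprinted genes rose and 4 fell. Over 19 other settings, Mest lost its call in 11 and Grb10 in 7, while Magel2 kept it in all. H19 was not analysed here.

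All 29 tested genes of ribosome biogenesis lay higher in mutant cells and 8 rose. Utp20, part of the machinery that processes ribosomal RNA precursors, rose from 8.53 ± 0.923 to 14.0 ± 0.867 FPKM, Rpf1 from 19.5 ± 0.283 to 27.1 ± 0.376 FPKM and Dkc1, the pseudouridine synthase dyskerin, from 20.9 ± 1.12 to 28.3 ± 0.145 FPKM. Over the other settings run, Utp20 and Rpf1 each lost their call in 6 of 19 and Dkc1 in 6 of 18. The list median was 0.35 (camera adjusted p = 2.3e-09; adjusted p = 0.26 with an estimated correlation), and without mutant column 0 the median was 0.30 and 5 rose. The 5 tested X-linked genes that escape inactivation had a median log2 fold change of -0.39 (camera adjusted p = 0.029; adjusted p = 0.28 with an estimated correlation), and 3 of them fell without mutant column 0. These lists were not rerun without the other libraries.

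Y-linked transcripts were present in the mutant libraries above their level in the wild-type libraries, and 38 of the 850 changed genes lie on chromosomes X or Y. Ddx3y measured 7.78, 46.1 and 36.0 FPKM in mutant columns 0, 1 and 2 against 0.157, 0.0281 and 0.450 FPKM in wild-type columns 0, 1 and 2, and Xist 37.3, 0.0176 and 0.0244 against 63.1, 64.6 and 65.9 FPKM. The labels do not give the sex of the embryos, and mutant column 0, with 16.8% of the highest Y-linked level and 57.7% of the wild-type Xist mean, may hold RNA of both sexes. If sex were the whole cause of the autosomal changes, mutant column 0 should show no more of them than its loss of Xist, 42.3%. At the median it showed 85.3% of the change of the other mutant libraries over 579 autosomal genes called without it (quartiles 55.9 and 116.4%). Over 12 p53 targets it showed 101.3%, and over 5 X-linked genes that escape inactivation 3.7%. The loss of Xist is on the FPKM scale and the shares are on the log2(FPKM + 1) scale, so 42.3% is not an exact bound. As this comparison rests on 1 library, sex and genotype cannot be told apart. With the Y-linked level as a covariate 478 genes changed, 201 of them among the 850. That covariate fit also rests largely on mutant column 0.

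A set of 41 genes was at 0 in all wild-type libraries with at least 1 FPKM in all mutant libraries, and 21 of them lie in the span annotated for Fgfr2. Of the 49 genes in that span, 100% were at 0 in all wild-type libraries and 0 were above 0 in any, which argues against lower transcription gene by gene and is consistent with failed quantification of the whole locus. Another 20 such genes do not lie wholly inside the span, of which Ctbp2, at 17.2, 16.1 and 17.1 FPKM in mutant columns 0, 1 and 2, overlaps its end and Gm18665, at 1.14, 4.71 and 4.48 FPKM, is on the Y chromosome. Loss of the span from the wild-type genome would not account for the remaining 18, on 11 chromosomes, but for the span itself it cannot be told apart. No biological explanation was tested beyond these. The opposite pattern, 0 in all mutant libraries with at least 1 FPKM in all wild-type libraries, was held by 9 genes. Rn7sk was among them, and the cause of that pattern was not tested.

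Erythroid and granulocyte markers were lower in the mutant libraries, with 9 of 9 tested members below all wild-type values. Fewer cells of every other type would lower the markers of all of them. Of the members of 7 other cell type lists 4 rose and 4 fell, and 4 of the 7 list medians were above 0, so these markers moved apart. The rises were 2 fibroblast and 2 adipocyte markers, and none of them passed without wild-type column 0, 1 or 2. Those fits had fewer libraries, so the lost calls do not speak against the rises. As the rises were few, the markers do not decide whether cells of every other type were fewer. Different amounts of carried-over blood could give the pattern and cannot be told apart from a genotype effect on these cells, since the markers move with the groups. The most abundant marker, Hbb-bs, measured 135, 158 and 136 FPKM in wild-type and 10.9, 35.6 and 13.4 FPKM in mutant columns 0, 1 and 2.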
